A study of Mus musculus with 12 samples.

How the data were processed

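The series holds 12 libraries of polyadenylated RNA from L3 to L5 dorsal root ganglia of wild-type mice, 6 after intra-articular NGF and 6 after vehicle. RNA was extracted with Trizol and a column kit for small samples, and libraries were made with a stranded mRNA kit, per the labels' protocols. Reads were processed with cutadapt, HISAT2 and StringTie on GRCm38, per the submitters' processing notes, which give no versions. The step that turned StringTie's output into whole counts, whether it used strand, and its treatment of reads with several matches are not given in the sources used here.

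The deposited count table gives whole-number counts of 55401 genes per library without normalization, per the file headers. A second deposited table gives FPKM values, a copy of the counts and gene coordinates for 37099 genes, per the file headers; the copied counts of these 37099 genes were identical to the count table in the 12 libraries. Both tables have further columns for 6 libraries that belong to no sample of this series, 18 columns of values in all, and these were not used here. Groups and replicate numbers were taken from the sample titles, and columns were matched to samples by the library names in the labels. Gene symbols and coordinates are those of the deposited FPKM table. Transcript length and GC content were taken from GENCODE M21, in which 36968 of its genes were found and 88.2% had identical coordinates; the longest transcript of each gene was used, and 20192 of 20216 tested genes had a value.

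Counts were analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 20216 of 35722 genes with a count, and library sizes were scaled by TMM. The test of NGF against vehicle was edgeR's quasi-likelihood F test with robust estimation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values per library are CPM after TMM scaling, given as mean ± SD, and log2 fold changes are NGF minus vehicle. The standard error of a fold change was derived from the fold change and the F statistic. The labels state no statistical method, so this design was set before the data were examined.

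For 36 gene lists, fixed before the data were examined, log2 CPM with a prior count of 2 was tested with camera in limma 3.58.1, with the preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. Camera compares a list with all other genes. Fry asks whether a list's genes move one way on balance. The mean of each list per library was compared by an exact permutation test over all 924 splits, two-sided. Calls of members are given over all genes and adjusted over the list alone. Overall separation was the mean squared difference of group means, compared with all 462 divisions into equal groups. Several lists share genes or are expressed by more than 1 cell type of the ganglion. A list of liver genes was added after the data were seen, to describe vehicle replicate 1.

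Genes are named by a rule fixed before the data were examined: the 10 largest rises and falls among called genes with a mean of at least 1 CPM, a panel of 12 genes, and for each list up to 4 called members with the smallest p, or 2 members where none was called. Members that passed only adjusted over the list alone, the marker genes of muscle and liver, and the genes given for chromosome or clock were named after their values were seen. Of the 43 called genes, 18 overlap another gene model, and ribosomal protein genes share sequence with pseudogenes. Since the use of strand is not given, the named genes that overlap another model are uncertain; among genes named in the other observations these are Celf4, Dclk1, Sema5a and Deptor.

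Depth was 59651178 to 66504223 counts per library. The biological coefficient of variation was 26.4%, so the spread between libraries, not counting error, limits precision for all but low genes. The procedure was tested on simulated data for this comparison, drawn from the real means and library sizes, with 19793 genes tested. EdgeR recovered 4% of genes changed by 1.25-fold, 64% of those changed by 1.5-fold, 90% of those changed by 2-fold and 96% of those changed by 4-fold, 50 genes each, with 7 false among 141 calls. DESeq2 made 34 false calls among 186, and limma-voom 3 among 134. With no change simulated the 3 tools called 0, 4 and 0 of 20216 genes. Camera found the 1 shifted list and 0 of 20 unshifted ones. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.95 (mitochondrially encoded genes). The simulation therefore cannot show false calls, of lists or genes, that arise from genes varying together or from trends shared by libraries.

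Alternatives set before the data were examined were other scaling factors, filters, DESeq2 1.42.0, limma-voom with and without quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, other thresholds, the replicate number as a block, 1 surrogate variable from sva 3.50.0, the pan-neuronal mean as a covariate, and each library left out in turn. Alternatives added after the data were seen were the removal of 3 libraries with liver or muscle transcripts, the red blood cell mean as a covariate, a smooth trend on length and GC content removed within each library (a local regression with span 0.3, entered as an offset in edgeR for genes and subtracted from log2 CPM for lists), a term for replicates 1 to 3 against 4 to 6, and list means with each library left out. Criteria of 2 technical tests were altered after a first run: for length and GC content the code was set to the written bound, from a stricter one, which changed its label, and for blood and marrow the bound in favour was widened to 2 SE, which changed none. A test of the gene models of Nnt was dropped after its result was seen, and their counts are given as values.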

Results

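Bulk RNA sequencing was used to compare gene expression in lumbar dorsal root ganglia (DRG) of mice after injections of nerve growth factor (NGF) or vehicle into the knee joint. DRG hold the cell bodies of the sensory neurons that supply the limb, together with satellite glia, Schwann cells, resident immune cells and vessels. NGF is a secreted protein that acts on sensory neurons through the receptors encoded by Ntrk1 and Ngfr. Wild-type males aged 15 weeks received 500 ng NGF or vehicle, 2 injections per week and 3 in total, and the L3 to L5 ganglia of the injected side were taken 24 hours after the last one. There were 6 NGF and 6 vehicle libraries. Each library held 59651178 to 66504223 counts assigned to genes, with 60355943 to 64467349 in the NGF group. Counts between libraries of a pair differed by far more than sampling noise for all 66 pairs (chi-square per gene 14.6 to 233), so no library was a repeat sequencing of another, and each was counted as 1 replicate. This test cannot tell libraries of different mice from repeat libraries of 1 mouse, and the labels do not say that each library came from 1 mouse, so p-values measure the spread between these samples.

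The first question was which genes differed in the ganglia after NGF. In edgeR's quasi-likelihood test, 43 of 20216 genes passed a Benjamini-Hochberg adjusted p of 0.05, 24 higher and 19 lower in the NGF libraries. The largest rise was that of Ptgir, the receptor for prostacyclin, at 98.0 ± 13.3 CPM in NGF against 53.7 ± 5.43 CPM in vehicle libraries (mean ± SD, n = 6 each; log2 fold change 0.87, SE 0.09, edgeR adjusted p = 0.00126). Its lowest NGF library (73.2 CPM) lay above its highest vehicle library (62.8 CPM). Rises were otherwise small, with a median log2 fold change of 0.43, and 18 of the 24 genes rose by less than 1.5-fold. The falls had a median of -0.88 and included several transcripts of myeloid blood cells.

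Etv5, an ETS transcription factor induced through the MAP kinase pathway, rose from 85.3 ± 11.9 to 136 ± 23.2 CPM (log2 fold change 0.67, edgeR adjusted p = 0.0406). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 23.4 ± 2.53 to 36.4 ± 6.39 CPM (0.64, SE 0.11). Irs2, an adaptor of the insulin receptor, rose by 0.60 (SE 0.10) on the log2 scale, and Ngfr, the low-affinity NGF receptor, from 540 ± 48.2 to 731 ± 91.7 CPM (0.44, SE 0.08). The thrombin receptor F2r (0.59, SE 0.11), the sphingosine 1-phosphate receptor S1pr3 (0.53, SE 0.09) and the cannabinoid receptor Cnr1 (0.50, SE 0.09) rose as well. Grid2ip, a scaffold protein of glutamate receptor synapses, rose from 5.03 ± 0.84 to 8.78 ± 1.16 CPM (0.80, SE 0.12). Mmp15, a membrane-type metalloproteinase, and Mbd6 completed the 10 largest rises at 0.52 and 0.46. Ptgir lies on chromosome 7 (16906490 to 16910905, GRCm38), Etv5 on chromosome 16 (22381309 to 22439719) and Ngfr on chromosome 11 (95568818 to 95587735).

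Of the 10 largest falls, 6 were in genes known from neutrophils and monocytes. S100a8, a subunit of calprotectin, fell from 23.5 ± 11.2 to 6.15 ± 1.48 CPM (log2 fold change -1.94, SE 0.28, edgeR adjusted p = 0.0387). Ifitm6 (-2.05), Chil3 (-1.92), Slfn4 (-1.82), Ly6c2 (-1.57) and Mmp9 (-1.48) fell as well, each from a vehicle mean under 10 CPM, with vehicle means of 2.14 CPM for Ifitm6 and 9.38 CPM for Chil3. Pi16, a gene of adventitial fibroblasts, fell as well (-0.88), and Npy1r, a receptor of neuropeptide Y expressed in sensory neurons, fell from 33.1 ± 4.86 to 21.7 ± 3.25 CPM (-0.61, SE 0.11). mt-Co3, a mitochondrially encoded subunit of cytochrome c oxidase, fell from 2615 ± 388 to 1863 ± 178 CPM (-0.49, SE 0.09). The fall of the pseudogene Rps12-ps3 (-0.51) is uncertain, since it shares sequence with Rps12 and lies antisense to Pdzd8. For the same reason the counts of mt-Atp6 and of its nuclear copy Gm10925 cannot be told apart with confidence. Grid2ip, Spry4, Irs2, S1pr3, Mbd6, Pi16 and Atp5l overlap other gene models, all on the other strand, and are uncertain to that extent, with at most 5.01% of the joint counts in the other model (Grid2ip); mt-Co3 borders on mt-Atp6.

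**Figure D1:**
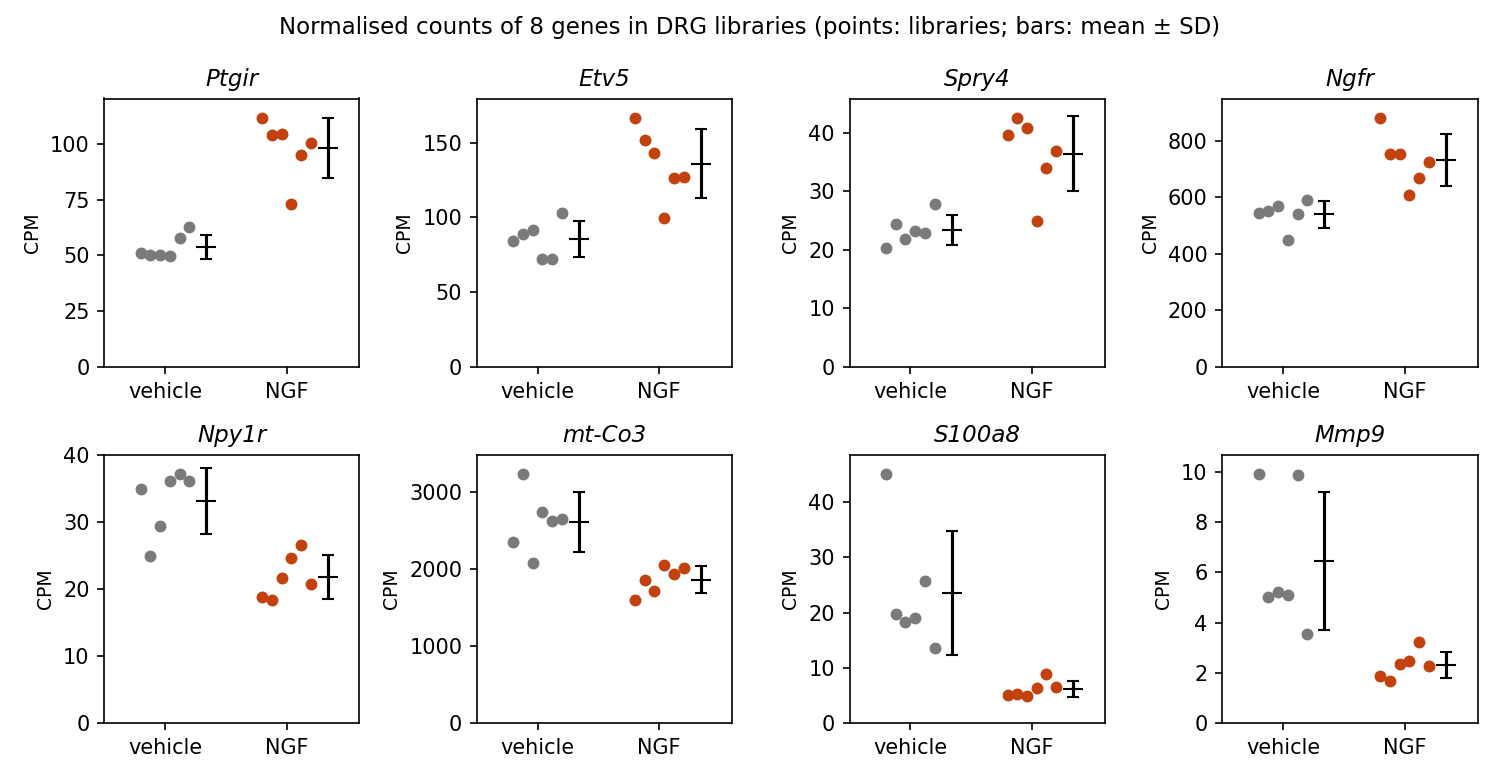
Normalised counts (CPM, linear axes from 0) of 8 genes, with 1 point per library and the mean ± SD of 6 libraries beside each group. Ptgir lay between 49.7 and 62.8 CPM in vehicle and between 73.2 and 111 CPM in NGF libraries, and S100a8 at 13.5 CPM or more in vehicle and 8.87 CPM or less in NGF libraries.

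The count of called genes depended on single libraries. It was 1 without NGF replicate 1, 2 or 3 or without vehicle replicate 5, 2 without NGF replicate 6 or vehicle replicate 2 or 4, 3 without NGF replicate 5, 12 without vehicle replicate 1, 24 without vehicle replicate 6, 71 without NGF replicate 4 and 781 without vehicle replicate 3. Ptgir stayed past the threshold with each of the 12 libraries left out, whereas S100a8 did so in 4 of them, Etv5 and Spry4 in 3 each, and Ngfr in 2. With the red blood cell mean as a covariate, added after the data were seen, none of the 43 was called. Differences were then 0.56 for Ptgir (edgeR adjusted p = 0.453), 0.34 for Etv5, 0.27 for Spry4 and 0.21 for Ngfr. The covariate itself differed between the groups (-0.88, SE 0.24), so its effect cannot be separated from that of NGF. Skeletal muscle transcripts were abundant in vehicle replicate 2 (Acta1 at 2680 CPM) and present in NGF replicate 2 (124 CPM), and liver transcripts in vehicle replicate 1 (Alb at 130 CPM). Without these 3 libraries edgeR called 0 genes, with 3061 at an unadjusted p under 0.05, and Ptgir differed by 0.82 with an adjusted p of 0.0862. With a term for replicates 1 to 3 against 4 to 6, added after the data were seen, the count was 1463, all 43 genes included.

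A panel of 12 genes of NGF signalling, nociception and nerve injury was fixed before the data were examined, and Ngfr was its only member to pass the main test. The other NGF receptor, Ntrk1, stood at 227 ± 22.6 CPM in NGF and 218 ± 29.0 CPM in vehicle libraries (log2 fold change 0.06, SE 0.08, edgeR adjusted p = 0.765). Values were also close for the nociceptor genes Calca (-0.09, SE 0.12), Trpv1 (0.10, SE 0.07) and P2rx3 (-0.07, SE 0.08) and the growth cone gene Gap43 (0.01, SE 0.08). The neurotrophin Bdnf (0.04, SE 0.18) and the chemokine Ccl2 (0.05, SE 0.28) were measured less precisely, Ccl2 at a mean of 1.62 CPM over all libraries. Scn10a, a voltage-gated sodium channel of nociceptors, had a log2 fold change of 0.30 (SE 0.10, edgeR adjusted p = 0.166), and Tac1, the precursor of substance P, one of -0.39 (SE 0.14, edgeR adjusted p = 0.213). These outcomes depend on the model: with the term for replicates 1 to 3 against 4 to 6 Scn10a passed (adjusted p = 0.0079), and with the DESeq2 test Scn10a (0.049) and Tac1 (0.0473) passed. With a length and GC trend removed neither passed, with Scn10a at 0.17 (adjusted p = 0.343) and Tac1 at -0.28 (0.379). The injury-induced genes Atf3 (-0.83, SE 0.33) and Sprr1a (-1.69, SE 0.97) had lower means in NGF libraries with adjusted p of 0.252 and 0.413. Vehicle replicate 5 was the highest library for both (23.8 and 5.70 CPM), and without it the values were -0.42 and -0.32. Sprr1a was near the detection floor at 1.40 ± 2.12 CPM in vehicle and 0.43 ± 0.30 CPM in NGF libraries.

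Whole pathways and cell types were compared with 36 gene lists fixed before the data were examined. By limma's camera with a preset correlation of 0.01, 5 lists were higher and 11 lower in NGF libraries at an adjusted p of 0.05. With a correlation estimated for each list camera called 0 lists, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.286. The directional test fry called 2 lists higher and 7 lower. In an exact permutation test of the list means over all 924 splits, 2 lists were lower, neutrophil markers and cell cycle genes, each at the smallest p the design allows (0.00216, adjusted p = 0.039). With 1 library left out this test called 0 lists in 7 of 12 analyses, and 0 without the 3 libraries with liver or muscle transcripts. A single list at the smallest possible p cannot pass the adjustment over 36 lists, so these lost calls can arise from the limited number of splits. With 1 library left out neutrophil markers still differed by -1.96 to -1.52 and cell cycle genes by -0.47 to -0.35. Without the 3 libraries the differences were -1.40 and -0.31.

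Genes of the NGF receptor and MAP kinase feedback list were higher by a mean of 0.16 log2 units (SE 0.07; camera adjusted p = 0.000108; adjusted p = 0.308 with an estimated correlation). The difference was 0.25 among replicates 1 to 3 and 0.07 among replicates 4 to 6. With the red blood cell covariate, which itself differed between the groups, the difference was 0.01 and the list was not called (camera adjusted p = 0.418). Of its 23 members, Etv5, Spry4 and Ngfr rose in the test over all genes, 0 fell and 20 did not pass. With a length and GC trend removed these called members no longer passed, at 0.61 for Etv5 (adjusted p = 0.062), 0.55 for Spry4 (0.0781) and 0.33 for Ngfr (0.0781). Adjusted over the list alone, 8 rose, including the phosphatase Dusp6 (0.35), the adaptor Shc1 (0.31) and the feedback inhibitors Spred2 (0.31) and Spry2 (0.29). The 34 pain-related ion channels were higher by 0.17 (SE 0.06; camera adjusted p = 1.25e-07; adjusted p = 0.308 with an estimated correlation), with 31 members above 0. None passed over all genes, and 7 rose adjusted over the list alone. Those with the smallest p were the potassium channels Kcnb1 (0.34, edgeR adjusted p = 0.0643) and Kcna2 (0.28, 0.0924), and Scn10a and Piezo2 were also among the 7. With the term for replicates 1 to 3 against 4 to 6, Kcnb1 (adjusted p = 0.00244), Kcna2 (0.00499) and Piezo2 (0.0283) passed over all genes. With a length and GC trend removed they did not pass, at 0.16 for Kcnb1 (adjusted p = 0.125), 0.17 for Kcna2 (0.191) and 0.09 for Piezo2 (0.491). Low-threshold mechanoreceptor and proprioceptor markers (0.13, SE 0.10, camera adjusted p = 0.00299) included Ntrk3 at 0.29 and Piezo2 at 0.24, with 0 of 20 members past either gene-level adjustment. The list differed by -0.04 among replicates 1 to 3 and by 0.30 among replicates 4 to 6, by 0.08 to 0.19 with 1 library left out and by 0.09 with a length and GC trend removed, and it was not called with the pan-neuronal covariate (adjusted p = 0.537). Axon growth and guidance genes (0.10, SE 0.06, camera adjusted p = 0.0109) had 29 of 43 members above 0, and 1 of them, Plxna4 (0.35, edgeR adjusted p = 0.0898), rose adjusted over the list alone. With an estimated correlation the adjusted p was 0.545 for either of these lists. The axon list was not called without NGF replicate 1 (adjusted p = 0.0522).

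Circadian clock genes were higher by 0.16 (SE 0.07, camera adjusted p = 0.0278; adjusted p = 0.485 with an estimated correlation). Of 17 members 0 passed over all genes, and 5 rose adjusted over the list alone: Per1 (0.39), Per2 (0.39), Per3 (0.48), Npas2 (0.41) and Ciart (0.71). This list was called in 7 of the 12 analyses with 1 library left out, and not without NGF replicate 2 or 3 or vehicle replicate 3, 5 or 6 (adjusted p 0.0521 to 0.0855).

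Neutrophil markers had the largest difference of any list called, with a mean of -1.77 log2 units (SE 0.37; camera adjusted p = 5.43e-17; adjusted p = 0.286 with an estimated correlation). All 15 members were lower in NGF libraries and all 15 fell adjusted over the list alone, of which S100a8 and Mmp9 also fell over all genes. The difference was -2.37 among replicates 1 to 3 and -1.17 among replicates 4 to 6. Genes of red blood cells moved with them, at -0.88 (SE 0.24, camera adjusted p = 1.01e-06), and differed by -1.47 among replicates 1 to 3 and by -0.28 among replicates 4 to 6, with Hbb-bs at 243 ± 55.6 CPM in vehicle and 116 ± 40.7 CPM in NGF libraries; 6 of 8 members fell adjusted over the list alone. Macrophage markers differed by -0.39 (SE 0.18, camera adjusted p = 2.84e-06), with 27 of 28 members below 0 and 5 that fell adjusted over the list alone, among them Lyz2 (-0.83) and Tyrobp (-0.81), both of which neutrophils also express. Cytokines and chemokines differed by -0.64 (SE 0.13, camera adjusted p = 0.00379), and 1 of 25, Il1b (-1.85, from 1.18 CPM in vehicle libraries), fell adjusted over the list alone. Interferon-stimulated genes differed by -0.50 (SE 0.24, camera adjusted p = 1.03e-06), with 4 of 26, including Ifi27l2a (-1.07) and Oas1a (-0.76), lower adjusted over the list alone. With an estimated correlation the adjusted p of these lists was 0.308 for red blood cells and cytokines, 0.477 for macrophages and 0.485 for interferon-stimulated genes.

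Cell cycle genes were lower, with a mean difference of -0.44 (SE 0.11, camera adjusted p = 3.09e-09; adjusted p = 0.286 with an estimated correlation). Adjusted over the list alone 9 of 23 fell, including Top2a (-0.91) and Mki67 (-0.62), with 0 past the test over all genes. Vehicle replicate 1 had the highest mean of cell cycle genes (1.65 log2 CPM) and of neutrophil markers (3.50), and NGF replicates 5 and 6 were the highest NGF libraries for both lists. Fibroblast and extracellular matrix genes differed by -0.25 (SE 0.11, camera adjusted p = 0.000137; adjusted p = 0.485 with an estimated correlation), with Pi16 lower over all genes and 2 of 27 adjusted over the list alone. Nerve injury and regeneration genes differed by -0.27 (SE 0.13, camera adjusted p = 0.00508; adjusted p = 0.485 with an estimated correlation), and by -0.18 without vehicle replicate 5. Their members with the smallest p were Stmn4 (-0.74, edgeR adjusted p = 0.0521), the 1 member of 33 to fall adjusted over the list alone, and Ptprn (0.27, 0.130).

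Genes of energy metabolism and translation were lower by small amounts across most members. All 13 mitochondrially encoded genes were lower, by a mean of -0.42 (SE 0.11; camera adjusted p = 5.11e-13; adjusted p = 0.308 with an estimated correlation). Of these, 2 fell over all genes, mt-Co3 and mt-Atp6, and all 13 adjusted over the list alone. All genes with a symbol starting with mt-, these 13 among them, took 3.66 ± 0.32% of counts in NGF and 4.88 ± 0.72% in vehicle libraries. Nuclear genes of oxidative phosphorylation differed by -0.20 (SE 0.06; camera adjusted p = 1.19e-21; adjusted p = 0.308 with an estimated correlation), with Atp5l (-0.39) and Ndufb4 (-0.33) lower over all genes and 46 of 73 adjusted over the list alone. For ribosomal protein genes the difference was -0.25 (SE 0.09; camera adjusted p = 4.00e-23; adjusted p = 0.308 with an estimated correlation), with 0 of 82 past the test over all genes, Rpl26 (-0.41, edgeR adjusted p = 0.0531) having one of the smallest p, and 53 lower adjusted over the list alone. Beside these lists the libraries differed in a trend with transcript length. Across 13970 genes, the rank correlation of a library's deviation from the mean with transcript length was 0.16 ± 0.15 in NGF and -0.15 ± 0.16 in vehicle libraries (exact permutation p = 0.00866, two-sided, n = 6 each). With this trend and that on GC content removed within each library, the differences were -0.25 for mitochondrially encoded, -0.12 for nuclear oxidative phosphorylation and -0.16 for ribosomal protein genes, and 0.08 for ion channels. All 4 lists were still called by camera, and the axon growth and circadian lists were not (adjusted p = 0.102 and 0.138). Of the genes, Atp5l stayed called (adjusted p = 0.0313), and mt-Co3 (-0.33, 0.156), mt-Atp6 (-0.30, 0.202) and Ndufb4 (-0.23, 0.0729) did not. Rpl26 passed (-0.30, 0.0322). The removal also bore on genes outside these lists, since 17 of the 43 called genes stayed called. Ptgir (adjusted p = 0.0159), Irs2 (0.0168) and Cnr1 (0.0393) were among them. Etv5 (0.062), Spry4 (0.0781), Ngfr (0.0781), S100a8 (0.0569) and Mbd6 (0.417) were not.

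**Figure D2:**
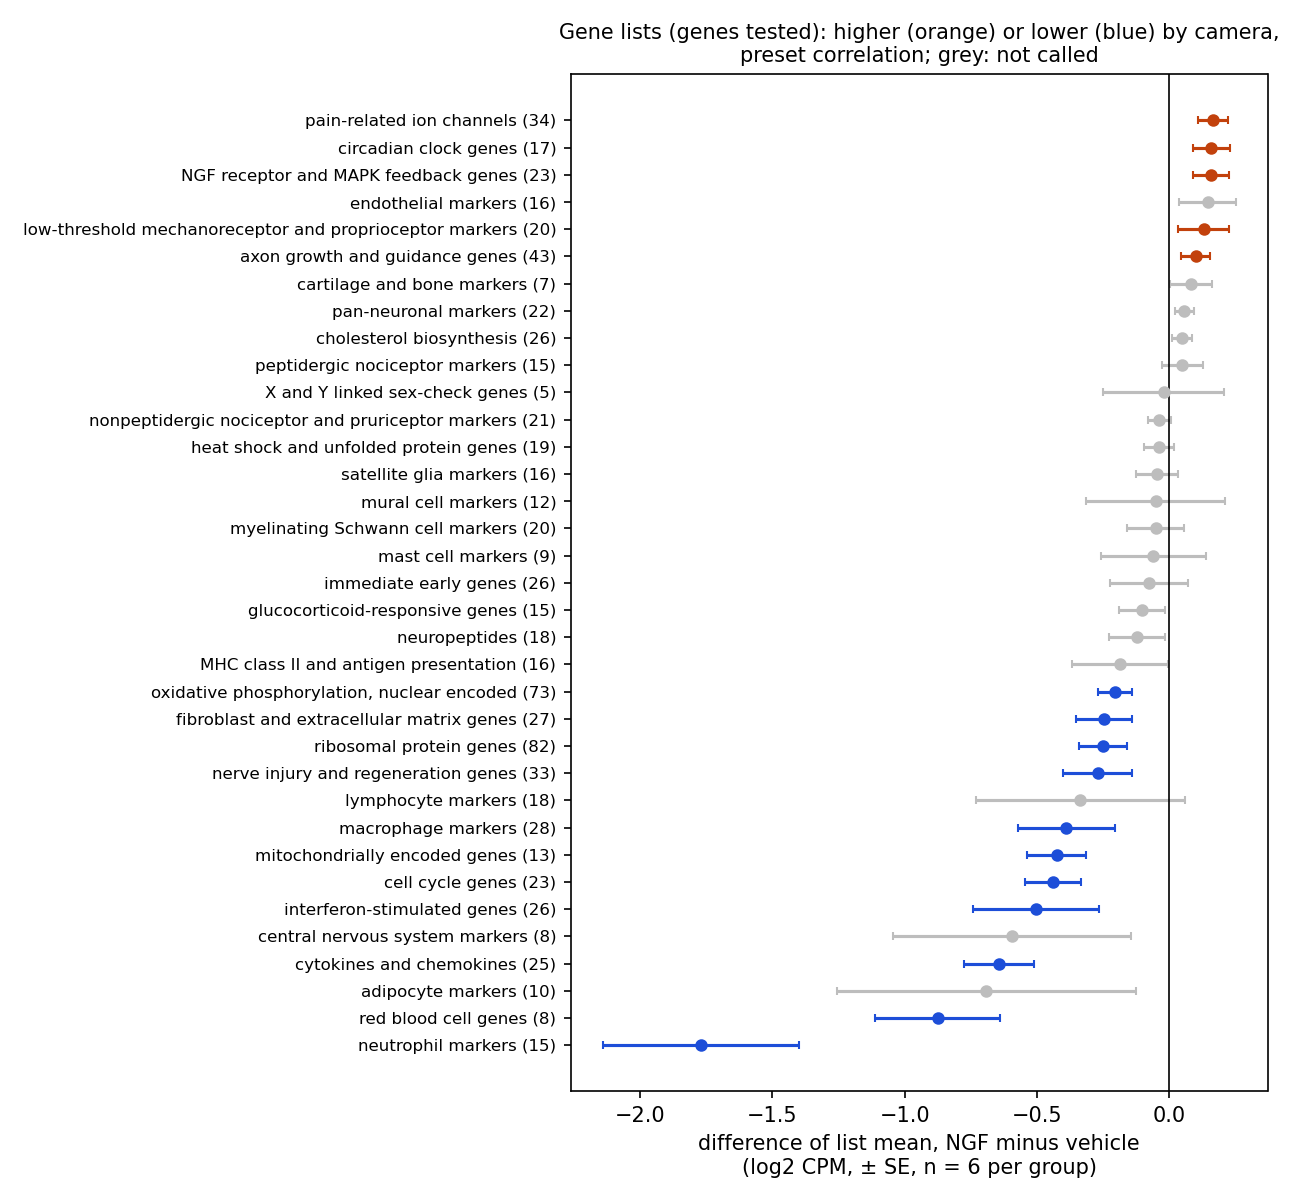
Difference of the mean log2 CPM of each gene list, NGF minus vehicle, with its SE over 6 libraries per group and the number of genes tested in brackets; orange lists were higher and blue lists lower by camera with the preset correlation, and 0 lists were called with an estimated one. Neutrophil markers stand at -1.77 and pain-related ion channels at 0.17; skeletal muscle markers (SE 2.05) are left out because vehicle replicate 2 sets their scale.

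Lists of other neurons and glia were not called. Differences were 0.05 for peptidergic nociceptor markers, in which Ptgir was the only gene called, -0.04 for nonpeptidergic nociceptor and pruriceptor markers, 0.06 for pan-neuronal markers and -0.12 for neuropeptides, with camera adjusted p of 0.538, 0.815, 0.0733 and 0.543. Peptidergic markers differed by 0.20 among replicates 1 to 3 and by -0.10 among replicates 4 to 6, and neuropeptides by 0.02 and -0.26. Satellite glia markers differed by -0.04 and myelinating Schwann cell markers by -0.05. In the satellite glia list the gap junction gene Gja1 stood at 0.30 (edgeR adjusted p = 0.0990). Gfap stood at -1.18 (0.163), from 2.89 CPM in vehicle libraries. Immediate early genes (-0.08), cholesterol biosynthesis (0.05), heat shock and unfolded protein genes (-0.04) and glucocorticoid-responsive genes (-0.10) were not called either. Of the remaining cell types, differences were -0.34 for lymphocyte, -0.06 for mast cell, 0.15 for endothelial and -0.05 for mural cell markers, -0.19 for MHC class II genes and 0.08 for cartilage and bone markers. Adipocyte (-0.69, SE 0.57), central nervous system (-0.59, SE 0.45) and skeletal muscle markers (mean -0.13, median -4.13) varied most between libraries. Camera's direction was up while mean and median were below 0 for satellite glia, mural cell and glucocorticoid-responsive genes. The sex-check genes differed by -0.02, and Ddx3y from the Y chromosome was present in all 12 libraries at 61.9 to 89.8 CPM.

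**Figure D3:**
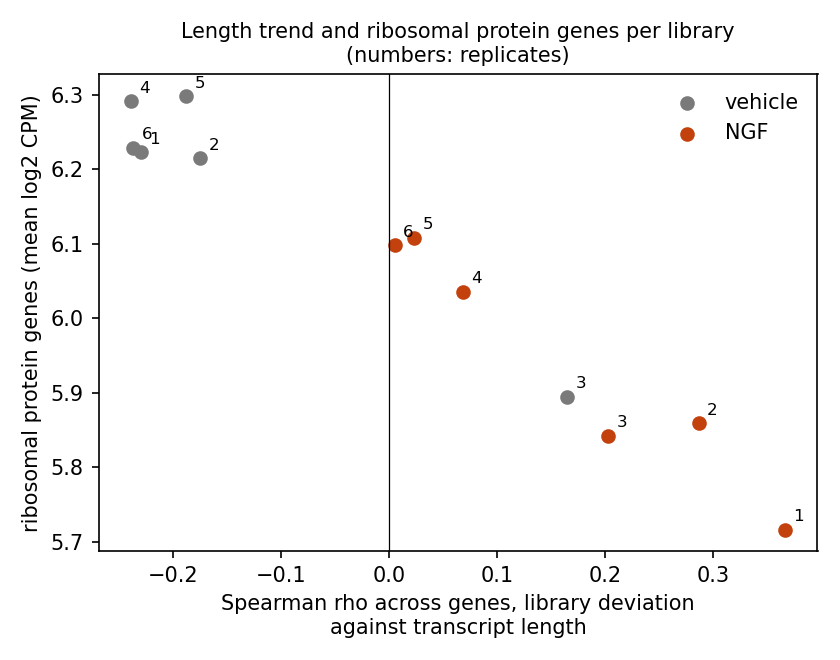
Mean log2 CPM of 82 ribosomal protein genes in each library (vertical) against the Spearman rho, across 13970 genes, of the library's deviation from the mean of all libraries with transcript length (horizontal); numbers are replicates. Vehicle replicate 3, at a rho of 0.17, lies among the NGF libraries (0.01 to 0.37), and the other vehicle libraries lie between -0.24 and -0.17.

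Taking all genes together, the squared difference between the group means averaged 0.116 per gene, against a median of 0.0877 over the 462 ways to divide the 12 libraries into 6 and 6. In 8 of these the value was as large (exact permutation p = 0.0173, one-sided). Among the 500 most variable genes p was 0.260. The first and second principal components held 20.1% and 13.4% of the variance.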

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

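The test of vehicle replicate 3 as a mislabelled library was chosen only after its effect on the count of genes was seen, the test of a length and GC trend for that library after its position was seen, and the red blood cell covariate after the data were seen. The criteria for blood, marrow and the length and GC trend were altered in code after a first run, and for the trend this changed the outcome.

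In 272 sets of 6 values (lists, named genes and library measures, each within 1 group), 23 held a library set apart from the other 5, by Dixon's outlier ratio at its 5% limit for 6 values. Chance gives about 1 in 20. Vehicle replicate 3 accounted for 8 of them. Its Spearman rho with transcript length was 0.17, against -0.24 to -0.17 in the other vehicle libraries, and its ribosomal protein genes had a mean of 5.89 log2 CPM, against 6.21 to 6.30. It was lowest for Rpl26 (136 CPM, others 168 to 182), for cytokines and chemokines (0.18 log2 CPM, others 0.74 to 1.04), for Tagln of smooth muscle (8.68 CPM, others 14.1 to 16.3), for Gfap (0.69 CPM, others 2.30 to 4.59) and for Mobp of central myelin (2.03 CPM, others 9.57 to 19.1), and highest for Ntrk3 (402 CPM, others 273 to 316).

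Vehicle replicate 2 was set apart by skeletal muscle markers, at a mean of 9.77 log2 CPM against at most 0.86 in the other vehicle libraries. Actn3 stood at 786 CPM, Casq1 at 278 CPM and Car3 at 734 CPM there. Its mural cell (3.59 log2 CPM) and endothelial markers (3.49) were also the highest of the vehicle group. NGF replicate 2 held Actn3 at 34.4 CPM and Casq1 at 14.9 CPM, above all other NGF libraries. In vehicle replicate 1, Lcn2 stood at 35.9 CPM, against 5.24 to 8.71 CPM in the rest of its group. Single values apart from their group were Hbb-bt in vehicle replicate 6 (85.2 CPM, lowest), Ngfr in vehicle replicate 4 (449 CPM, lowest), Grid2ip (11.05 CPM, highest), Mbd6 (46.8 CPM, highest) and Tyrobp (1.52 CPM, lowest) in NGF replicate 3, and Sprr1a in NGF replicate 1 (listed at 0 CPM).

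The first pattern weighed was the lower level of neutrophil and monocyte genes in NGF libraries, by -1.77 ± 0.37 (SE) on the log2 scale, and by -0.88 with red blood cell genes as a covariate. It did not rest on 1 vehicle library, since the difference closest to 0 with any of them left out was -1.52 (SE 0.31). Bone marrow carried over at dissection predicts that genes of immature granulocytes fall as much as those of mature neutrophils. The immature genes used were Mpo, Elane, Prtn3, Ngp, Camp, Ltf and Ctsg. They differed by -1.64 (SE 0.43) against -1.74, which met the bound set in favour of that source. The fall was uneven, with Mpo at -0.98, Prtn3 at -1.52, Ltf at -1.91, Ngp at -1.98, Camp at -2.06 and Elane at -2.25. Elane and Prtn3 stood at 2.41 CPM or less in every library. Blood alone predicts an equal fall of haemoglobin, and that difference, -1.03 (SE 0.27), lay between the bounds set for and against it, so blood cannot be told apart from marrow by this value. Fewer myeloid cells in the ganglia after NGF stay open as a biological explanation that these libraries do not test.

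The second pattern was the lower level of 86 mitochondrially encoded and nuclear respiratory chain genes, with a median log2 fold change of -0.22. Removal of a smooth trend on transcript length and GC content left a median of -0.13 (SE 0.01 over genes), past the written bound of -0.11 by 1.54 SE. That SE treats genes that vary together as independent. Between libraries the mean difference of these genes had an SE of 0.07 before the removal, wider than the distance from -0.13 to -0.11. The trend may thus account for part of the difference, and this test cannot decide whether it is the whole. The mean of these genes with the trend removed within each library still differed, by -0.14 (exact permutation p = 0.00866, n = 6 per group). Muscle in vehicle replicate 2 was argued against by a median of -0.20 without that library, and a lower share of neurons by pan-neuronal markers that were higher by 0.058 (SE 0.035). A treatment effect stays open as a hypothesis, as do differences between libraries that no label records.

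The third pattern was the rise of the count of called genes from 43 to 781 without vehicle replicate 3. Over the 200 genes with the smallest p in that analysis, its median position between the other vehicle libraries (0) and the NGF libraries (1) was 0.82 (SE 0.03). Left-out NGF libraries lay at 0.47 to 1.39 and other left-out vehicle libraries at -0.04 to 0.38. Each of these was placed over the 200 genes of its own analysis, in which vehicle replicate 3 counted as vehicle, so the positions are not over the same genes. A mislabelled NGF library is therefore a candidate explanation. NGF replicate 4, the lowest of the NGF libraries at 0.47, was the library closest to vehicle replicate 3 (chi-square per gene 18.2). That closeness does not speak for an exchange of these libraries, which would place them in opposite groups. NGF replicate 4 was also nearer to NGF replicates 5 and 6 (20.2 and 20.8) than to vehicle replicates 4 to 6 (57.8 to 66.3), with vehicle replicate 1 at 27.9. An exchange was not tested otherwise. Neutrophil markers (1.92 log2 CPM) and Ptgir of vehicle replicate 3 were within the range of the other vehicle libraries. They were outside that of the NGF libraries (at most 1.17 for neutrophil markers). Both were chosen for this comparison because they separated the groups, although the neutrophil list was fixed before the data were examined. That separation did not rest on vehicle replicate 3, since both were called with each of the 12 libraries left out (edgeR for Ptgir, camera with the preset correlation for the list). Their values go against a mislabelled library and the median position goes with one, so whether vehicle replicate 3 is mislabelled is not decided. With a trend on length and GC content removed its position stayed at 0.72 (SE 0.05), above the lowest NGF library at 0.45, which argues against the trend as the cause, but weakly, since vehicle replicate 6 at 0.51 (SE 0.03) also lay above it.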

How the results depend on the processing

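The red blood cell covariate, the removal of 3 libraries, the length and GC trend, the term for replicates 1 to 3 and list means with libraries left out were chosen only after the data were seen.

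All 43 genes kept their direction in every alternative that tested them. Their number stayed between 50 and 62 with other scaling, other filters on counts or 1 surrogate variable. It was 703 with the DESeq2 test (292 higher), 6 with limma-voom, 132 with quality weights, 12 without robust estimation, 1 on log2(FPKM + 1), 37 on log2(FPKM + 0.1) (7 higher, 30 lower, against 24 and 19) and 0 on log2(FPKM + 1) without a filter, with 3419 genes at an unadjusted p under 0.05. It was 252 at an adjusted p of 0.1, and 261 at an unadjusted p under 0.05 with at least 2-fold change, of which 29 were higher. With pan-neuronal markers as a covariate 2 genes were called. Whether replicate numbers pair these samples is not settled, since the titles give them only as sample numbers. Same-number correlations ranged from 0.0109 to 0.353, and 2 NGF and 3 vehicle libraries correlated best with their own number. With the replicate number as a block 547 genes were called, all 43 included, and Atf3 (adjusted p = 0.044) and Scn10a (0.0254) passed. With the red blood cell covariate 1 gene was called, which was none of the 43, and log2 fold changes were smaller for most called genes named in the report, such as 0.56 for Ptgir (adjusted p = 0.453), 0.34 for Etv5, 0.27 for Spry4, 0.21 for Ngfr and -1.11 for S100a8, and larger for Pi16 (-0.94) and Ndufb4 (-0.37). This covariate itself differs between the groups (-0.88), so its effect cannot be separated from that of NGF. The count without the 3 libraries with liver or muscle transcripts was 0 (fewer samples; 3061 at an unadjusted p under 0.05), with the length and GC trend removed 19, of which 17 were among the 43, and with a term for replicates 1 to 3 against 4 to 6 1463. Leaving out 1 library gave 1 to 781 genes: 1 without NGF replicate 1, 2 or 3 or vehicle replicate 5, 2 without NGF replicate 6 or vehicle replicate 2 or 4, 3 without NGF replicate 5, 12 and 24 without vehicle replicates 1 and 6, 71 without NGF replicate 4 and 781 without vehicle replicate 3. Ptgir was called in 28 of 31 alternatives. The cause of the changes was not tested otherwise.

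Of 36 lists, camera called 16, fry 9 and camera with an estimated correlation 0, where 5 had an unadjusted p under 0.05; in the other alternatives it called 14 to 20. Calls were lost with the pan-neuronal covariate for low-threshold mechanoreceptor (adjusted p = 0.537), axon growth (0.241) and fibroblast lists (0.137), on log2(FPKM + 1) for cytokines (0.149), and with the red blood cell covariate for the NGF receptor and MAP kinase list (0.418) and axon growth (0.401), besides the red blood cell genes themselves. Exact permutation of list means called 2 lists, 0 without the 3 libraries (fewer samples and splits; neutrophil markers still differed by -1.40), and 0 to 9 with 1 library left out: 0 in 7 of 12 analyses (smallest adjusted p 0.0649 to 0.0779) and 9 without vehicle replicate 3. A single list at the smallest possible p cannot pass the adjustment over 36 lists. Neutrophil markers still differed by -1.96 to -1.52 with 1 library left out. Lists that turned and were called after the turn were peptidergic nociceptor markers (-0.17) and cholesterol biosynthesis (-0.060) with the red blood cell covariate, and skeletal muscle markers, at 1.16 without the 3 libraries, and from -1.04 to 1.59 with 1 library left out, highest without vehicle replicate 2, which holds the muscle transcripts. In 39 other list results camera's direction changed with no call before or after. Overall separation had an exact permutation p = 0.260 among the 500 most variable genes (n = 6 per group). At this depth and spread small changes are mostly missed: edgeR recovered 4% of the smallest simulated changes.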

Other observations

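The test against other splits was set before its result was seen; the divisions by replicate number were examined after the data were seen.

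Several called genes outside the lists and the 10 largest changes were named after their values were seen. Genes that rose in NGF libraries included Nptx1, a neuronal pentraxin (log2 fold change 0.46), the microtubule-associated kinase Dclk1 (0.34), the RNA-binding protein Celf4 (0.38) and the guidance molecule Sema5a (0.36). Luzp1 (0.42), Mapk11, a p38 kinase (0.28), and Deptor, an inhibitor of mTOR (0.27), rose as well, as did Sox10, the transcription factor of peripheral glia, from 40.5 ± 3.40 to 51.0 ± 2.73 CPM. Mmp14 (0.40) rose beside Mmp15, and Abcc4, a transporter that exports cyclic AMP, by 0.39. Gpx3, an extracellular glutathione peroxidase, fell from 81.9 ± 10.8 to 58.7 ± 3.51 CPM. All of these passed the edgeR test at adjusted p of 0.0341 to 0.0487.

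Other splits of the 12 libraries into 6 and 6 were tested for the count of genes. Of 100 splits, the real one included, 1 gave as many as 43 genes, which was the real one, and the highest other gave 1, which argues against chance assignment of the labels as the source of the count.

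Replicates 1 to 3 and 4 to 6 differed in the trend with GC content in both groups. The Spearman rho of a library's deviation with GC content was 0.15 to 0.28 in NGF replicates 1 to 3 and -0.01 to 0.09 in NGF replicates 4 to 6, and 0.08 to 0.24 against -0.37 to -0.31 in vehicle libraries (exact permutation within groups over 400 regroupings, p = 0.005, adjusted p = 0.02 over 4 measures). Rho with length differed as well (adjusted p = 0.02), although its ranges overlapped among vehicle libraries, and the first and second principal components did not (adjusted p = 0.167 and 0.62). Called genes numbered 1463 with a term for this division, against a highest of 422 and a median of 25 for the other divisions among 50 drawn of 200 possible. Within replicates 4 to 6 alone, 3 libraries against 3, edgeR called 2195 genes, and within replicates 1 to 3 it called 70. The libraries with liver or muscle transcripts and vehicle replicate 3 are all among replicates 1 to 3. Chi-square per gene was 35.1 to 199 between vehicle replicates 1 to 3 and 14.6 to 24.7 between vehicle replicates 4 to 6. These counts of called genes therefore cannot tell a batch from a wider spread among replicates 1 to 3. The labels name no batch.

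Xist was counted 427 times in vehicle replicate 1 and at most 70 times in any other library, of mice recorded as male. Counts of Gm42878 (chromosome 5, 121518613 to 121545482, GRCm38) ranged from 0 to 16.3 CPM among vehicle libraries. The overlapping gene models of Nnt, on chromosome 13 (119335448 to 119408997), took 96 to 1008 and 0 to 662 counts per library, while their sum stayed between 641 and 1008.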
